A study of Folsomia candida with 8 samples.

How the data were processed

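The files described 8 two-colour Agilent arrays of a Folsomia candida expression design, 4 per diclofenac concentration, each with RNA of exposed and of clean-soil animals in opposite dyes. Per the labels' protocols, adults were age-synchronised, exposed in jars at 20 °C, floated out of the soil with water and frozen, and total RNA was extracted from all animals of a jar. Labelled cRNA was made from 500 ng. The treatment protocol gives about 30 g of soil per jar and the series design 25 g, and which was used is not settled here. The submitters call the 4 arrays of a concentration biological replicates. Groups and dyes were taken from each channel's labels.

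The scanner files hold spot intensity values on a linear scale, deposited by the authors as extracted by Agilent Feature Extraction, with mean foreground and median local background per channel. Per the file headers the extraction software was version 10.5.1.1, while the submitters' processing notes name 9.5.1.1. The processed signals in these files were background-subtracted and dye-normalized by that software, and its log10 ratio of Cy5 over Cy3 is deposited beside them, per the file headers. The authors also deposited a table of log2 ratios of the same arrays, for which the submitters' processing notes name limma without steps. Set against the scanner values, it proved to hold Cy5 over Cy3, unturned for the dye swap. It correlated across spots at 0.890 to 0.935 with the scanner's log ratio, at slopes of 0.635 to 0.713, and at 0.984 to 0.993 with the values computed here. Its column medians were 0.0073, 0.0034, -0.0019, 0.011, -0.0026, 0.014, 0.0097 and 0.0071 for EC10 replicates 1 to 4 and EC50 replicates 1 to 4. The exact normalization behind it is not given in the sources used here.

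Before the data were examined, the following steps were fixed. Background was corrected with normexp (offset 50), ratios were normalized by loess within each array with control spots at weight 0, outlier spots (3.56% to 3.83% of an array) were left out, and the 3 spots of a probe were averaged. No spot was saturated. Ratios were turned to exposed over control. A probe was tested if at least 0.5 of its spots were well above background in the exposed or control channel on at least 3 of the 4 arrays of a concentration, which 4374 of 5069 probes met. A linear model with a coefficient for EC10, for EC50 and for dye was fitted to the 8 arrays with limma 3.58.1 (statmod 1.5.0, R 4.3.3) using lmFit and eBayes, and p was adjusted by Benjamini-Hochberg at 0.05. All tests were two-sided. An SD is that of the 4 arrays and an SE that of the model. The arrays were on 1 slide read in 1 scan, and by their recorded positions the concentrations lay in different columns of it, so concentration and slide position cannot be told apart.

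Of the 5069 probes, 2321 carry a best hit and 2748 none in the deposited descriptions, and 1063 hits name a product by the rule used. The given reference table was not used for names, since the files' hits are proteins of other species. For each concentration, the text names the 10 largest rises and 10 largest falls among passing probes with a product name and the same sign on all 4 arrays, 1 probe per description. It adds up to 2 highest and 2 lowest passing members of each list, and the 5 largest differences each way between concentrations. Where fewer than 5 pass in a direction, those with the smallest p complete 5, given as values that did not pass. Probes without a name are limited to 2 rises and 2 falls. Which descriptions count as naming a product (clone numbers and systematic names do not) was refined after the data were seen.

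Keyword lists on the descriptions, 27 in number, were fixed before the data were examined. They cover detoxification, stress, metabolism, protein turnover, hormones, tissues and other organisms. The 23 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. With fry, no list moved one way on balance in any comparison, while 13 lists at EC10, 5 at EC50 and 0 between the concentrations passed its mixed test, which takes changes in either direction together. That test does not say which members changed, and fry does not compare a list with other probes.

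That control RNAs were shared between the concentrations was found from the data and is not stated in the labels. Control channels were matched by the correlation of their normalized levels across probes, only between channels in the same dye. Fits with control RNA as a random block (duplicateCorrelation, consensus correlation 0.523 with the dye term and 0.708 without) and without both arrays of the control RNA with the lowest Cy3 signal were therefore chosen after seeing the data. The median residual SD was 0.329 with the dye term and 0.436 without. The correlation expected with no effect was simulated by drawing each group's mean from random mixtures of the measured deviations between RNAs, with the 4 control RNAs shared or independent. Parts of the arrays that share no control RNA were simulated in the same way with 2 arrays per concentration.

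The procedure was tested on simulated data with each probe's residual spread from the fit with the dye term, a dye bias and independent arrays, so without the shared controls. That spread leaves out any difference between control RNAs that the dye term took up, so the recovered shares may be too high. Each comparison had 1 simulated data set of 4374 probes, of which 67, 67 and 66 were changed 1.5-, 2- and 4-fold. Of these, 37.3%, 67.2% and 95.5% were recovered for EC10, 41.8%, 62.7% and 95.5% for EC50, and 14.9%, 35.8% and 86.4% for the difference. Alternatives were no background correction, the scanner's processed signals, median centring, Aquantile, other filters, outlier spots kept, no dye term, concentrations apart, a variance trend with robust estimation, array weights, the authors' table, other thresholds and each array left out.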

Results

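The series measured transcripts of the springtail Folsomia candida, a soil arthropod used in standard toxicity tests, after exposure to diclofenac, a non-steroidal anti-inflammatory drug, in a natural sandy standard soil (LUFA 2.2). It asked which transcripts differ from those of animals in clean soil at the concentrations that lower reproduction by 10% (EC10) and by 50% (EC50). About 30 adults aged 23 days were kept for 2 days in each jar, and RNA of whole animals was hybridised on 8 two-colour arrays, each setting exposed RNA directly against control RNA. There were 4 arrays per concentration, stated by the submitters to be biological replicates, with the exposed RNA in Cy5 on 2 arrays of each concentration and in Cy3 on the other 2. Each array held 15207 spots of 5069 probes. Between 77.9% and 88.1% of the spots of a channel were well above background, and the median net signal ran from 198.8 to 571.8 in Cy3 and from 468.5 to 836 in Cy5. The number of arrays limits the precision. A probe was named here by its best sequence hit in the deposited description, often from a distant species, so a name stands for a similar protein and not for an established springtail gene. Positions in the genome were not analysed here.

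The control channels fell into 4 pairs. The control RNA of EC10 replicate 1 matched that of EC50 replicate 3, EC10 replicate 2 matched EC50 replicate 4, EC10 replicate 3 matched EC50 replicate 1, and EC10 replicate 4 matched EC50 replicate 2. Levels of the 4374 tested probes correlated at 0.9989 to 0.9993 across probes within these pairs, against 0.937 to 0.978 between the 8 other pairs of control channels in the same dye and at most 0.988 between exposed channels. Matches were sought only between control channels in the same dye. By this matching the arrays held 4 distinguishable control RNAs, numbered 1 to 4 below in this order. Control RNAs 1 and 2 were in Cy3 and control RNAs 3 and 4 in Cy5. Mean levels of control RNAs in different dyes correlated at 0.915 to 0.950, below the matched pairs. Whether the same RNA was used in both dyes, with levels shifted by dye, was not tested. Dye and control RNA therefore cannot be separated. The lowest Cy3 signals, 198.8 and 203.2, were those of control RNA 1.

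At EC10, the named transcripts that rose most were similar to a lectin and to an antimicrobial peptide, while the immunity and blood cell list did not shift (7 members, median -0.71, adjusted p = 0.79). Fcc02343, a hit to gastrodianin, an antifungal mannose-binding lectin of an orchid, rose 7.74-fold (log2 change 2.95 ± 0.29, SD, n = 4; SE 0.23; adjusted p = 0.0048). Fcc05968, a hit to the beetle antimicrobial peptide Alo2, rose 4.76-fold (log2 change 2.25 ± 0.63, SD, n = 4; SE 0.33; adjusted p = 0.028). Fcc05235, a hit to the extracellular matrix protein alpha-tectorin, fell by 1.72 on the log2 scale (± 1.15, SD, n = 4; adjusted p = 0.042). Fcc02328, a hit to the plant peptidyl-prolyl isomerase ROC4, an enzyme class that assists protein folding, fell by 1.38 (± 0.73, SD, n = 4; adjusted p = 0.044).

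Another 8 named probes rose by less at EC10. DNA topoisomerase I, which relaxes supercoiled DNA (Fcc06037), rose by 0.93 log2 units and cervical cancer protooncogene 5 (Fcc03177) by 0.92. A translation factor whose deposited name is cut short (Fcc04121) rose by 0.71, a bacterial serine/threonine kinase hit (Fcc01253) by 0.69 and a DNA mismatch repair hit (Fcc02956) by 0.67. A cytochrome P450, an oxidase family active on drugs and hormones (Fcc00299), rose by 0.65, the Msx1 homeobox hit (Fcc05362) by 0.61 and Serrate, a Notch ligand of flies (Fcc06048), by 0.57. Their adjusted p lay between 0.025 and 0.050, with the 4 arrays positive in each. Several of these ratios were uneven across the control RNAs: DNA topoisomerase I read 1.90 and 1.45 against control RNAs 1 and 2 and 0.16 and 0.19 against control RNAs 3 and 4. A glutathione S-transferase theta 1 hit (Fcc01652) passed with a fall of 0.73, with 3 of the 4 arrays negative. Hits to the extracellular matrix protein fibulin 2 (Fcc05158) at -0.88 and to the FIP1L1/PDGFRA fusion protein (Fcc05500) at -0.48 did not pass (adjusted p = 0.063 for each). With control RNA as a random block, 7 of the 8 smaller rises no longer passed (adjusted p from 0.063 to 0.093), while protooncogene 5 did (0.028). Nor did the alpha-tectorin (0.081), ROC4 (0.075) and glutathione S-transferase (0.085) hits (Fcc05235, Fcc02328, Fcc01652). Among probes with no product name, Fcc01531 rose by 2.85 and Fcc05840 by 1.98. Fcc02255, with the probe sequence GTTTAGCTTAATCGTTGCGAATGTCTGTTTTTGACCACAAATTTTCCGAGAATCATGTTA, fell by 3.50 (adjusted p = 0.0014). Fcc02934 fell by 2.32 and was above background in the exposed channel on 2 of the 4 arrays. With the block, Fcc01531 (adjusted p = 0.063) and Fcc02934 (0.092) did not pass.

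Across the array, 140 of the 4374 probes passed at EC10 (limma with Benjamini-Hochberg adjustment), 103 higher and 37 lower, and 1254 had an unadjusted p under 0.05. Of the 140, 24 named a product, 52 changed at least 2-fold and 77 had the same sign on all 4 arrays. The change was larger against control RNAs 1 and 2 than against control RNAs 3 and 4 in 133 of the 140, with median sizes of 1.53 and 0.25 log2 units. The count was 25 with control RNA as a random block and the dye term kept, 1 without the dye term, 1 with the block and no dye term, and 0 in fits that took each concentration alone (775 unadjusted) or gave the variance a robust trend (1246 unadjusted). Without both arrays of control RNA 1 it was 9. Fcc02343 was the single probe that passed with and without the dye term and the block. Leaving out single arrays left 9, 4, 38 and 8 probes without EC10 replicates 1 to 4, and 7 and 53 without EC50 replicates 1 and 2. Without EC50 replicates 3 and 4, 128 and 84 passed. Fcc02343, Fcc02255, Fcc04611 and Fcc02760, the last chosen after its values were seen, passed in all 8 of those fits.

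At EC50, hits to 2 lectins and to an antimicrobial peptide rose most among the named probes, and the immunity and blood cell list did not shift (median 0.0062). Fcc01429, a hit to actinohivin, a mannose-binding lectin of an actinomycete, rose 12.8-fold (log2 change 3.68 ± 1.30, SD, n = 4; SE 0.33; adjusted p = 0.0059). The gastrodianin hit Fcc02343 rose 10.4-fold (3.38 ± 0.67, SD, n = 4; adjusted p = 0.0015). The Alo2 hit Fcc05968 rose 8.46-fold (3.08 ± 0.83, SD, n = 4; adjusted p = 0.0091). Fcc02552, a hit to the receptor kinase fms-related tyrosine kinase 1, rose 2.11-fold with little spread between arrays (1.08 ± 0.12, SD, n = 4; adjusted p = 0.0059).

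Another 6 named probes rose by smaller amounts. Apolipophorin, the lipid carrier of insect blood (Fcc02219), rose by 1.48 log2 units. The alpha 1 subunit of the glycine receptor, a chloride channel (Fcc01574), rose by 1.35, with the control channel above background on 3 of 4 arrays. Ribosomal protein S19e (Fcc00886) rose by 1.24 and a group 2 mite allergen (Fcc03269), from a lipid-binding protein family, 2.14-fold. A crayfish PAPI I hit (Fcc01108) rose by 1.05 and a twin-arginine translocation signal hit (Fcc03114) by 0.96, again with 3 of 4 control channels above background. The adjusted p of these 6 lay between 0.015 and 0.037, and the 4 EC50 arrays were positive in each. For S19e the ratio was 2.36 and 2.29 against control RNAs 1 and 2 and 0.078 and 0.22 against control RNAs 3 and 4. The allergen hit read 1.75 and 2.34 against 0.045 and 0.25 in that order. Named probes that fell past the threshold were absent from the EC50 calls. The lowest p among named probes with a negative change belonged to hits to retinal-binding protein (Fcc03889, -0.51, adjusted p = 0.083), the FIP1L1/PDGFRA fusion protein (Fcc05500, -0.44), glutathione S-transferase theta 1 (Fcc01652, -0.60), NAD+ synthase (Fcc03874, -0.69) and lola like (Fcc05368, -0.51). Among unnamed probes, Fcc04611, with the sequence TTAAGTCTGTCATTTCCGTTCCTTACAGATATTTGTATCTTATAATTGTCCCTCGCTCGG, rose by 2.82 (adjusted p = 0.00015) and Fcc02190 by 2.66 (adjusted p = 0.0015). Fcc02202 and Fcc02703 each fell by 0.81.

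**Figure D1:**
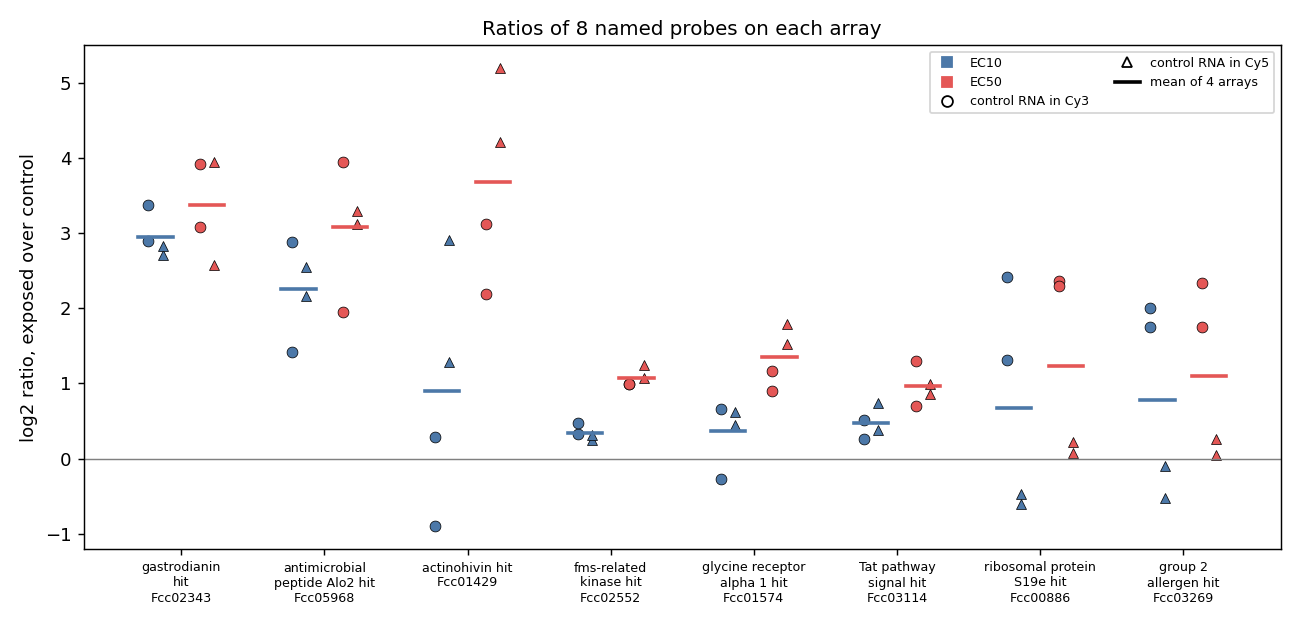
Log2 ratios of exposed over control RNA (vertical axis) for 8 named probes, with a point for each array, EC10 in blue and EC50 in red, circles for control RNA in Cy3 and triangles for control RNA in Cy5, and a bar at the mean of 4 arrays. The gastrodianin hit lies between 2.58 and 3.94 on all 8 arrays, while S19e reads 2.36 and 2.29 on the EC50 circles and 0.078 and 0.22 on the EC50 triangles.

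In all, 58 probes passed at EC50, 53 higher and 5 lower, with 775 at an unadjusted p under 0.05. Of the 58, 14 named a product, 37 changed at least 2-fold and 42 had the same sign on all 4 arrays. Median sizes were 1.64 against control RNAs 1 and 2 and 0.68 against control RNAs 3 and 4. With control RNA as a random block and the dye term kept 41 passed, but the PAPI I and twin-arginine hits did not (adjusted p = 0.055 and 0.054), nor did the unnamed Fcc02202 (0.086). Without the dye term 14 passed, 7 with the block as well, and without both arrays of control RNA 1, 11 did. Named rises that did not pass without the dye term were those of apolipophorin (Fcc02219, adjusted p = 0.58), S19e (Fcc00886, 0.74), the allergen (Fcc03269, 0.74) and PAPI I (Fcc01108, 0.063), and the unnamed falls of Fcc02202 (0.74) and Fcc02703 (0.40) did not pass either. The glycine receptor and twin-arginine hits (Fcc01574, Fcc03114) passed (0.036 and 0.035), but not with the block and no dye term (0.16 and 0.24). The gastrodianin, Alo2 and fms-related kinase hits passed with and without the dye term and the block. The actinohivin hit passed in each of the 8 fits without 1 array but not without the dye term (adjusted p = 0.071) or without both arrays of control RNA 1 (0.054). The count was 0 when EC50 was fitted alone (725 unadjusted), 14 with a robust variance trend, and 6, 8, 9 and 15 without EC50 replicates 1 to 4. The Alo2 hit did not pass without EC50 replicate 1 or 2, nor the fms-related kinase hit without EC50 replicate 1.

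The direct comparison of EC50 with EC10 asked whether the transcripts responded differently at the higher concentration, and no probe passed. The lowest adjusted p was 0.12, 263 probes had an unadjusted p under 0.05, and a fit without the dye term also gave 0 (118 unadjusted). Among named probes, the EC50 change exceeded the EC10 change by 2.78 log2 units for the actinohivin hit (Fcc01429, SE 0.46, adjusted p = 0.26), by 0.74 for the fms-related kinase hit (Fcc02552, SE 0.14, adjusted p = 0.39) and by 0.98 for the glycine receptor hit (Fcc01574, SE 0.23). It exceeded it by 2.06 for alpha-tectorin (Fcc05235, SE 0.45) and by 2.33 for a second group 2 allergen (Fcc04297, SE 0.55). The opposite sign was read for Msx1 (Fcc05362, -0.50), the bacterial kinase hit (Fcc01253, -0.70), Nijmegen breakage syndrome 1, a DNA break repair protein (Fcc05934, -0.58), protooncogene 5 (Fcc03177, -0.55) and a T54-like protein (Fcc00731, -0.54). None of these passed in this fit, which does not pair the arrays by control RNA. It therefore did not show that responses called at a single concentration differed between concentrations. With control RNA as a random block, which removes its spread from this comparison, 5 unnamed probes passed, and 8 did so without the dye term. The 8 included the fms-related kinase and second allergen hits. With the block and the dye term, the adjusted p was 0.058 for the actinohivin hit, 0.071 for the fms-related kinase hit and 0.106 for the second allergen hit, none past the threshold. Differences taken between the arrays of each control RNA, tested with limma, gave 0 (535 unadjusted).

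Many of the same probes were called at both concentrations. Of 103 higher probes at EC10 and 53 at EC50, 23 were shared, against 1.25 for independent lists of those sizes, and 4 of the 37 and 5 lower probes were shared, against 0.042. Unchanged groups simulated with the shared control RNAs gave a median of 0 shared calls, and 3 of 100 draws gave 27 or more. In the 6 draws with calls at both concentrations, between 68.1% and 100% of the shorter list was shared, against 46.6% here. Each simulated control RNA was a random mixture of the measured deviations, so the real alignment of control RNAs with dye was not kept. These draws therefore do not settle how often the shared control RNAs would give such an overlap. No probe was called in opposite directions. The changes correlated across probes at r = 0.627 (Spearman 0.579), where probes are not independent replicates. Unchanged groups simulated with the shared control RNAs gave a mean r of 0.612, with 95% of 1000 draws between -0.017 and 0.947. These draws did not keep the alignment of control RNAs with dye either. The covariance was 0.12 against a simulated mean of 0.0712 (95% of draws between -0.00103 and 0.258), a difference of 0.0488, and 17.1% of draws were as large. Each concentration was also cut to 2 arrays, 1 per control dye, that shared no control RNA with those of the other. The 4 splits of this kind gave r between 0.277 and 0.492. Splits of control RNAs 1 and 2 against control RNAs 3 and 4 were not computed. Single EC10 and EC50 arrays of opposite dye orientation correlated at -0.333 to 0.199. Those of the same orientation with different control RNAs correlated at -0.045 to 0.517, and those that shared a control RNA at 0.266 to 0.846. Arrays of the same concentration in opposite orientation correlated at -0.046 to 0.640 at EC10 and at -0.173 to 0.142 at EC50. In the same orientation they correlated at 0.460 and 0.144 at EC10 and at 0.234 and 0.531 at EC50. Part of the overlap of calls may come from the shared control RNAs.

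**Figure D2:**
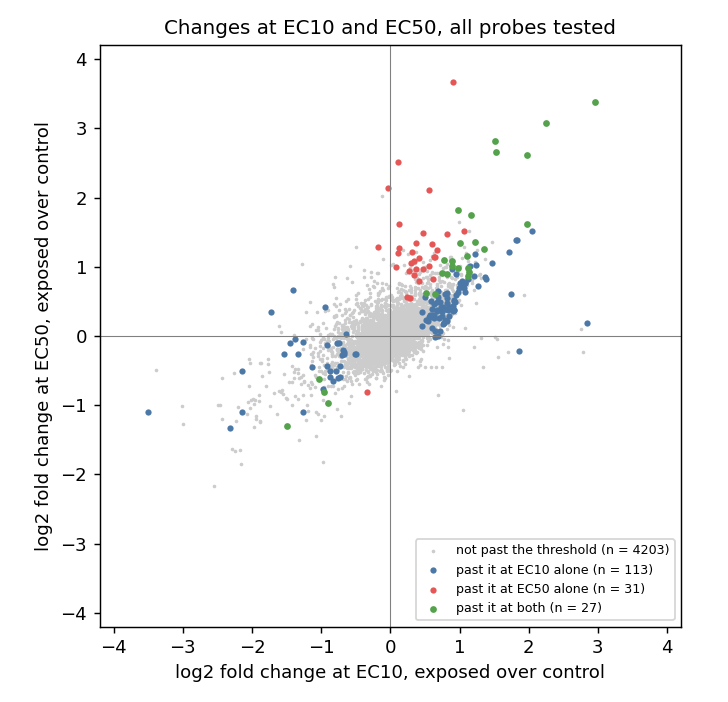
Log2 fold change at EC10 (horizontal axis) against EC50 (vertical axis), exposed over control, with a point for each of the 4374 tested probes coloured by whether it passed an adjusted p of 0.05. The 27 probes that passed at both concentrations lie in the quadrants where both changes have the same sign, 113 passed at EC10 alone and 31 at EC50 alone, and r across probes was 0.627.

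Among the gene lists, the oxidative phosphorylation list, which holds subunits of the mitochondrial respiratory chain and of ATP synthases, was the only one of 23 tested that shifted at EC50 (camera, 14 members, median log2 change 0.32, adjusted p = 0.0056), and it did not pass with an estimated correlation (adjusted p = 0.90). None of the 14 passed alone over all probes, and 6 were higher when adjusted over the list alone. Members chosen after their values were seen were NADH dehydrogenase subunit 4L (Fcc00588, 0.91, SE 0.24) and NADH dehydrogenase subunit 4 (Fcc04995, 0.87, SE 0.17), respiratory complex I proteins with hits to another springtail. The list's adjusted p was 0.45 after median centring and 0.068 without both arrays of control RNA 1. It had a median of 0.16 at EC10 (adjusted p = 0.33). At EC10, no list passed, with 2 at an unadjusted p under 0.05 and none with an estimated correlation or with fry for a shift in one direction. In fry's mixed test, 13 lists passed at EC10. With camera, the lowest adjusted p at EC10 was 0.23, for glutathione S-transferases, conjugating enzymes of detoxification. Their 16 members had a median of -0.20, with 1 lower, and 2 lower adjusted over the list alone. At EC50 their median was -0.0025, with none past the threshold and 3 lower adjusted over the list alone. Without EC10 replicate 1 the EC10 shift of this list passed at the preset correlation, toward lower levels (adjusted p = 0.0096), as did that of the gut digestion list (adjusted p = 0.037).

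The other detoxification and stress lists did not shift in one direction. In fry's mixed test, which does not compare a list with other probes, 3 of them passed at EC10. These were cytochrome P450 (adjusted p = 0.0086), transporters (0.0068) and antioxidant defence (0.0070), and the last also passed at EC50 (0.016). Cytochrome P450 (11 members) had medians of -0.030 at EC10, with Fcc00299 higher, and 0.020 at EC50, with 2 members higher at EC10 adjusted over the list alone. Transporters (11) had medians of 0.12 and 0.11, esterases and short-chain dehydrogenases (13) of -0.12 and 0.069, and chaperones (9) of -0.048 and 0.12, with no member past the threshold. Antioxidant defence (12) had medians of -0.15 and 0.26, with 1 member higher and 1 lower at EC10 adjusted over the list alone. The glucuronosyl and sulfotransferase list had 1 tested member (-0.52 and -0.087), lower at EC10 at an unadjusted p under 0.05. Over all probes, 1254 of the 4374 reached that at EC10. The keywords of the list for prostanoid metabolism, the target pathway of the drug in vertebrates, matched no description, nor did those for apoptosis and DNA repair. Neither list was therefore tested, and repair-related hits under other words were on the array (Fcc02956, Fcc05934).

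Metabolism and protein synthesis gave similar results. Glycolysis and the TCA cycle (6) had medians of -0.21 at EC10 and 0.081 at EC50, and lipid metabolism (23) of -0.16 and 0.093. The cytosolic ribosome (33) had medians of -0.18 (adjusted p = 0.28) and 0.023, with S19e higher at EC50 and 2 members higher there adjusted over the list alone. After median centring its shift at EC10 passed, toward lower levels (adjusted p = 2.6e-05), but not with an estimated correlation, either with loess (0.82) or after median centring (0.96). Translation factors (8) had medians of 0.23 and 0.38, with Fcc04121 higher at EC10. Adjusted over the list alone, 2 were higher and 1 lower at EC10 and 1 higher at EC50. The proteasome and ubiquitin list (17) had medians of -0.18 and -0.052, with 2 members lower at EC10 adjusted over the list alone. Cell cycle and DNA replication (5) had medians of 0.28 and 0.14, with topoisomerase I higher at EC10 and 3 members higher there adjusted over the list alone.

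Hormone, tissue and other-organism lists also stayed short of the threshold with camera at each concentration. Ecdysteroid and juvenile hormone genes (5) had medians of -0.20 and -0.022, with 1 lower at EC10 adjusted over the list alone, and beta-lactam biosynthesis (4), an antibiotic pathway, of -0.098 and 0.40, with 1 higher at EC50 on that basis. Development signalling had 1 tested member (0.24 and -0.034). Muscle (8) had medians of 0.11 and 0.050, cuticle and chitin (6) of -0.18 and -0.14, yolk and egg (3) of 0.096 and 0.15, and gut digestion (17) of -0.19 and 0.25. Immunity and blood cells (7) had medians of -0.71 and 0.0062, with the Alo2 hit higher at each concentration and 1 member lower at EC10 adjusted over the list alone. That list passed fry's mixed test at EC10 (adjusted p = 0.0068) and at EC50 (0.00026). The nervous system list (14) had medians of 0.11 and 0.22, Wolbachia and bacteria (7) of -0.028 and 0.10, and fungi and yeast food (15) of -0.12 and -0.040. Adjusted over the list alone, 1 member of the nervous system, bacterial, fungal and yolk lists was higher at EC50, and 1 cuticle member was lower at EC10. The median, mean and test differed in sign for 3 lists at EC10 (beta-lactam, cuticle, yolk) and 6 at EC50 (esterases, chaperones, lipid, ecdysteroid, cuticle, fungi).

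Between EC50 and EC10, 2 lists differed in the direction of higher levels at EC50. The cytosolic ribosome list had a median difference of 0.24 (33 members, adjusted p = 0.00013) and the gut digestion list of 0.30 (17 members, adjusted p = 0.0087), with no single member past the threshold. With an estimated correlation the adjusted p was 0.65 for each, and no list passed. With control RNA as a block they were 5.0e-05 and 0.0093. The gut digestion difference also did not pass without EC10 replicate 2 (adjusted p = 0.30), without EC50 replicate 2 (0.064) or with array weights (0.16). Without EC10 replicate 1, 6 lists differed. Relative to the mean of the RNAs in the same dye, the digestion list's median level was -0.47 and -0.42 in EC10 replicates 2 and 4 and 0.48 and 0.34 in EC50 replicates 2 and 4. It was 0.13 and -0.098 in EC10 replicates 1 and 3 and 0.055 and 0.0084 in EC50 replicates 1 and 3. The immunity list, which did not pass this comparison (adjusted p = 0.22), moved with it over the 12 RNAs (r = 0.925). Members chosen after their values were seen were a serine protease (Fcc04075, -0.63 at EC10 and 0.84 at EC50) and a cellulase (Fcc05266, -0.14 and 0.64), neither past the threshold. Here the median, mean and test differed in sign for 4 other lists.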

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

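Among the tests in this part, those of the dye term, of the shared control RNAs and of other splits of the samples were chosen after the results were seen.

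Of 86 groups of 4 arrays tested for an array that stands apart, 3 had one, against 4.3 expected by chance. The unnamed probe Fcc01531 read 1.29 on EC10 replicate 1 and 3.34 to 3.38 on the other EC10 arrays. The fibulin 2 hit Fcc05158 read -1.57 on EC50 replicate 3 and -0.32 to -0.20 on the other EC50 arrays. The unnamed probe Fcc02190 read 2.04 on EC50 replicate 1 and 2.81 to 2.91 on the others.

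The group 2 allergen hit Fcc04297 was lower on all 4 EC10 arrays (-0.70, -2.68, -0.38 and -1.36) and higher on all 4 EC50 arrays (1.49, 0.23, 1.65 and 0.83). The difference of 2.33 did not pass the test of the difference (adjusted p = 0.66). The cytosolic ribosome list differed between the concentrations by a median of 0.24 and the gut digestion list by 0.30 (adjusted p = 0.65 for each with an estimated correlation). Of 34 splits of the 8 arrays, the real one included, 11 gave as many lists as the 2 found here, and the highest other split gave 7, so chance was not excluded by these splits, which ignore the pairing of arrays by control RNA. Within the 4 pairs the ribosome median was higher at EC50 in 4 of 4 (by 0.11, 0.32, 0.14 and 0.32) and the digestion median in 3 of 4 (-0.096, 0.54, 0.15 and 1.07). The adjusted p were 5.0e-05 and 0.0093 with control RNA as a block. In differences within pairs they were 7.24e-05 and 0.0103, and 0.799 for each with an estimated correlation. The 8 splits within pairs are too few for a share under 0.05. The real count was 2 lists in those differences and with the block, 4 of the 8 splits reached it in each, and the highest other gave 6 and 4. The split that followed dye orientation could not be estimated.

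With control RNA as a random block, 5 probes without a hit differed between the concentrations (adjusted p from 0.028 to 0.031). Fcc04611 differed by 1.31, Fcc00738 by 1.37, Fcc02255 by 2.40, Fcc02565 by 2.06 and Fcc00545 by -2.09, the 5 being named after their values were seen. There are 8 splits of this kind, too few for a share under 0.05, and 1, the real one, gave as many. The highest other gave 1. Without the block, 0 probes passed in the real split, which all 34 splits reach by definition, and the highest other gave 1. In differences taken within the 4 control RNA pairs, 0 passed (535 at an unadjusted p under 0.05), which all 8 splits reach by definition, and the highest other gave 1.

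More probes passed with a dye term than without it, 140 against 1 at EC10 and 58 against 14 at EC50. The term passed for 787 probes. With the control RNAs paired in the other 2 ways it passed for 0 each time, and 1 and 10 or 1 and 7 probes were called. A dye bias of the probes would act on exposed and control RNA alike, but the SD across probes of Cy5 minus Cy3 in the exposed RNAs was 0.351 of that in the control RNAs (0.23 against 0.66), which argues against it as the main source. An effect of dye limited to the control channels is not separated from a difference between control RNAs. The control RNAs held 89.0% of the variance of these differences, which restates the same SDs and adds no further support. The differences were between means of 2 control RNAs and of 4 exposed RNAs per dye, so sampling alone would also make the control SD larger. The dye term may largely hold the difference between control RNAs 1 and 2 and control RNAs 3 and 4. If so, the counts with the dye term leave out part of the spread between controls, also where control RNA was a block (25 and 41). Without the dye term the counts were 1 and 14, and 1 and 7 with the block. No biological explanation of the difference between control RNAs was tested.

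The changes at EC10 and EC50 correlated across probes. The covariance of 0.12 lay inside the range simulated for unchanged groups with shared control RNAs, -0.00103 to 0.258. In the 4 splits with a control RNA of each dye in each part, parts that shared no control RNA correlated at 0.277 to 0.492. These values lay inside the range simulated for such parts of unchanged groups, -0.772 to 0.776 in 95% of draws. Splits of control RNAs 1 and 2 against control RNAs 3 and 4 were not computed. Both ranges were wide. They rest on 4 control RNAs and on random mixtures that did not keep the alignment of control RNAs with dye. Shared controls and a shared response to the drug therefore cannot be told apart here.

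For the counts at each concentration there are 8 ways to turn the sign of the ratio on some of the 4 arrays, too few for a share under 0.05. The real count was 140 at EC10 and 58 at EC50, each reached by 1 of the 8, and the highest other was 0 for each. For lists at EC10 the real count was 0, which all 8 reach by definition, and the highest other was 8. For lists at EC50 the real count was 1, 3 of the 8 reached it and the highest other was 1.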

How the results depend on the processing

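The fits with control RNA as a block, those without both arrays of control RNA 1 and the differences within control RNA pairs were chosen after seeing the data, as were the alternatives for lists differing between the concentrations. The cause of a change with a setting was not tested unless it is given.

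With median centring, 520 probes passed at EC10 and 123 at EC50, 1 list shifted at EC10 (cytosolic ribosome, lower) and 0 at EC50. With median centring and an estimated correlation, also chosen after seeing the data, 0 lists shifted at EC10 and at EC50 and 0 differed between the concentrations. Without the dye term 1 and 14 probes passed, and with a robust variance trend 0 and 14. With the concentrations apart, which leaves fewer arrays per fit, 0 and 0 passed (775 and 725 at an unadjusted p under 0.05). With array weights 852 passed at EC50, 527 higher and 325 lower, 13 differed between the concentrations, and the correlation of changes was 0.464. At an adjusted p under 0.1 the counts were 654 and 153, and under 0.01, 4 and 13. With an estimated correlation 0 lists shifted at EC50 and 0 differed between the concentrations. With control RNA as a block and the dye term, 25 probes passed at EC10 and 5 differed between the concentrations. With the block and no dye term, 1 passed at EC10, 7 at EC50 and 8 in the difference. Without both arrays of control RNA 1, 9 and 11 passed, r was 0.456, 1 list shifted at EC10 (glutathione S-transferases, lower, adjusted p = 0.0065 at the preset correlation) and 0 at EC50. An estimated correlation was not used in that fit. With all arrays it gave this list an adjusted p of 0.82 at EC10.

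Leaving out each array in turn gave 4 (without EC10 replicate 2) to 128 probes at EC10, 6 (without EC50 replicate 1) to 46 at EC50, and 0 to 2 in the difference, 2 without EC10 replicate 4. The correlation lay between 0.475 (without EC50 replicate 3) and 0.674 and was 0.482 without EC10 replicate 1. It gave 0 to 2 lists at EC10, 2 without EC10 replicate 1, and 1 list at EC50 each time (adjusted p from 0.0026 to 0.048). Between the concentrations 1 to 6 lists differed, 6 without EC10 replicate 1, 1 (cytosolic ribosome) without EC10 replicate 2 or EC50 replicate 2, and 3 without EC50 replicate 4, against 2 with all arrays. With array weights 1 differed (cytosolic ribosome), and with median centring 3 did. Without EC10 replicate 1, EC10 replicate 4 and EC50 replicate 1, 9, 8 and 7 probes passed at EC10, and without EC10 replicate 3, EC50 replicate 2 and EC50 replicate 4, 38, 53 and 84. Without EC50 replicates 2, 3 and 4, 8, 9 and 15 passed at EC50.

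The counts stayed within 1.5 times of 140 and 58 with no background correction (142 and 63), the scanner's processed signals (146 and 46), the authors' table (136 and 55), no filter (117 and 50), the strict filter (142 and 49), outlier spots kept (111 and 58) and a 1.5-fold minimum (129 and 56). The probes called were not all the same. Of the 140 at EC10 and 58 at EC50, 94 and 38 were called again with the scanner's processed signals. With no filter 106 and 46 were, and with the strict filter 129 and 48. With the authors' log2 ratios 122 and 51 were, and with no background correction 132 and 58. With outlier spots kept 111 and 58 were, and with a 1.5-fold minimum 129 and 56. Aquantile leaves ratios as they are and says nothing about stability. Over 1195 pairs of 1 of 48 named results and a setting, Aquantile left out, 858 kept direction and side of the threshold, 323 kept the direction and no longer passed, 14 newly passed, and 0 reversed. The 48 include results that did not pass in the main fit, and the 858 count these wherever they again did not pass. All 323 losses fell on results that passed in the main fit, so the pooled 858 overstates how stable those calls were. The Cy3 signals of control RNA 1 (198.8 and 203.2) were the lowest.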

Other observations

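In this part, the test of channel brightness was set before its result was seen, and the other tests were chosen after.

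The digestion and cuticle lists spread more between exposed RNAs of one kind than most random lists of probes. The gut digestion list spread more between control RNAs of one dye than 98.28% of 10000 random lists matched in size and level, and more between exposed RNAs of one concentration and dye than 99.96%. The exposed spread of cuticle and chitin genes lay at 99.85% and that of immunity genes at 99.43%, while their control spread lay at 87.02% and 39.42%. The cytosolic ribosome stood at 3.13% between control and 0% between exposed RNAs, and the proteasome list at 2.54% and 1.77%. Muscle lay at 98.04% between exposed RNAs and beta-lactam biosynthesis at 97.55% between control RNAs. Adjusted over the 46 percentiles of 23 lists, the exposed spread of the ribosome (adjusted p = 0.0092), digestion (0.023) and cuticle (0.0491) lists passed. That of the immunity list did not (0.133), nor did the control spread of digestion (0.259) or any other of the 46. These p come from randomly drawn probes and so take list members as independent. The estimated correlation between members was 0.29 for digestion, 0.12 for the ribosome and -0.075 for cuticle. The p therefore do not measure variation between RNAs, of which each concentration and dye held 2. Among single probes chosen after their values were seen, the log2 difference of control RNA 1 minus 2 (in Cy3) and of control RNA 3 minus 4 (in Cy5) was -1.92 and -3.21 for a serine proteinase (Fcc04942). It was -2.98 and -1.90 for a xylanase (Fcc04469), -1.93 and -2.60 for lipase H (Fcc03348) and -3.87 and -0.42 for elongation factor 1 alpha (Fcc05454).

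The digestion and immunity lists moved together over the 12 RNAs (r = 0.925, permutation p = 3e-05, adjusted p = 0.00066 over 22 relations; Spearman 0.909, permutation p = 0.00016, adjusted p = 0.00337), and r was 0.892 without the 2 RNAs farthest from the median. A list's level is its median log2 level relative to the mean of the RNAs in the same dye. The permutations here and below take the RNAs as exchangeable. Exposed and control levels of an array come from the same spots, and centring by dye ties the RNAs together. The p of these relations may therefore be too small. EC10 replicates 2 and 4 were lowest in both lists, at -0.47 and -0.42 for digestion and -0.43 and -0.94 for immunity. EC50 replicates 2 and 4 were highest, at 0.48 and 0.34 and at 1.03 and 0.61. Ecdysteroid and juvenile hormone genes also followed digestion (r = 0.870, adjusted p = 0.00275), as did lipid metabolism, with 1 member shared with the digestion list (0.783), beta-lactam biosynthesis (0.773), glutathione S-transferases (0.742), cytochrome P450 (0.710), glycolysis and the TCA cycle (0.704) and antioxidant defence (0.674). The adjusted p of these last 6 lay between 0.0189 and 0.0394. Cell cycle genes ran against it (-0.700, adjusted p = 0.0309). The cuticle and chitin list, which bears on moulting, did not follow digestion past the threshold (0.40, adjusted p = 0.255), nor did the other 12 lists (adjusted p of 0.0666 or more).

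A difference between the groups is argued against as the sole source, since centring within control, EC10 and EC50 left r at 0.870 (exact p = 0.00448, adjusted p = 0.00897 over 6 relations). Of the other 5 relations recomputed in this way, the ecdysteroid, lipid, beta-lactam and glutathione S-transferase relations passed (r from 0.656 to 0.865). The cell cycle relation did not (r = -0.654, exact p = 0.0523; -0.416 without the 2 farthest), and the cytochrome P450, glycolysis and antioxidant relations were not recomputed. By the rule set beforehand, brightness of the channel was also argued against. The digestion list followed it at r = 0.254 (permutation p = 0.425, Spearman 0.224, r = 0.328 without the 2 farthest). With 12 RNAs such an r is only loosely determined, and the list levels had been normalized, so brightness is not excluded. The immunity list was not set against brightness. The labels do not record the feeding or moulting state of the animals, and no biological explanation was tested.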
